A study of Mus musculus with 8 samples.

How the data were processed

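RNA was measured in 8 libraries of gastric epithelial cells sorted from the stomachs of C57BL/6 mice, 4 from mice fed a high fat diet (HFD) and 4 from control mice. Per the labels' protocols, total RNA was purified from the sorted cells, treated with DNase, freed of ribosomal RNA with a RiboMinus system for low input and made into unbarcoded libraries with the Ion Total RNA-Seq kit. Such libraries keep RNA without a poly(A) tail, so histone, small nucleolar and other structured RNAs are measured together with messenger RNA, and ribosomal RNA that escapes removal takes part of the reads. The submitters' processing notes name the genome build mm10 and bedtools 2.17.0, without saying what each was used for. The aligner, the annotation and the normalization method are not given in the sources used here.

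Each library has its own deposited table of 38920 rows, in the same order in every table, with 1 column of values, headed normalize, whose unit the sources used here do not give. The authors' deposited values were read as log2 values, because their antilogs sum to the same total in every library. They are floored at 0, and a value of 0 was taken as 0 on the linear scale. On the linear scale the 8 libraries sum to 36.9 M each, within 0.0039% of each other, so the authors' values are scaled to a common total. Of the row identifiers, 35720 are plain gene numbers, of which 32891 matched the RefSeq gene table of GRCm38.p6, the same assembly as mm10, 2748 begin with NEWGENE, and 452 have another form. Coordinates are those of that table, counted from 1. The NEWGENE rows have no gene name in the sources used here.

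Depth was estimated from a step taken as the worth of 1 read. The step was the most frequent low value of the library, or a whole fraction of that value. The fraction was chosen by the share of NEWGENE rows that became whole multiples. The estimates are 35.6, 31.4, 46.0 and 38.2 M reads for HFD 22, 23, 26 and 27, and 53.3, 32.4, 16.4 and 63.2 M reads for control 15-17-18, 16, 19 and 20. Their median, 36.9 M, lies at the common total. Between 24.3% and 34.9% of the values below 2000 steps were whole multiples of the step within 0.01, so whole reads were not recovered, no count model was fitted, and no counting interval is given. Control 19 is the shallowest library by this estimate. Control 15-17-18 is deeper but has more rows at 0, 16479 against 12399 in control 19. Which library has the least precise low values was not tested.

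Groups were taken from the sample titles. The labels do not say whether each library came from 1 mouse. The title of control 15-17-18 lists 3 numbers and may stand for a pool, which the labels do not state. P-values therefore measure the spread between these libraries. No replicate number is shared between the groups, so nothing was paired, and the labels give no batch or date. Pairwise Spearman correlations over all rows ran from 0.845 to 0.980, so no libraries held identical values. Pairs with HFD 23 ran from 0.845 to 0.896 and those without it from 0.910 to 0.980, so HFD 23 was the least like the others by this measure.

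The design written before the data were examined foresaw counts or per-million values. The tables hold log2 values, and the test foreseen for values without counts was used. Where several rows shared a symbol, the row with the highest total was kept, which left 38892 rows. The 27380 rows with a linear value of at least 1 in at least 4 libraries were tested with limma 3.58.1 (trend and robust options, R 4.3.3) on log2(value + 1), with the group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes on this scale understate the change of low genes. Of the tested rows, 23746 carry a gene symbol. In all, 39 gene lists were fixed beforehand, and the 38 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The list of mitochondrially encoded genes had 1 tested member and was left out. Of these lists, 17 hold markers of cell types that the sorted cells could include. Each library's mean log2 value over a marker list was compared between groups with an exact two-sided permutation test over the 70 ways of dividing the libraries, for which the smallest p is 0.0286.

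After the data had been seen, a median-ratio scaling was added, in which each library is divided by the median ratio of its rows to the row means, over the 11107 rows above 30 in all 8 libraries. It was added because the common total leaves the median tested row 0.90 higher in HFD on the log2 scale. After this scaling the shift is 0.12. Unless the deposited scale is named, levels and differences below are log2(value + 1) after this scaling, and therefore relative to the typical gene.

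Genes were named by a rule written before the data were examined. It takes called genes with a mean value of at least 5 and with all 4 HFD libraries on 1 side of all 4 controls, up to 8 per direction; with fewer than 5 in a direction, the smallest p-values under the same conditions fill up to 6, said to have missed the threshold. From each list described it takes up to 3 called members, or the 2 with the smallest p. It adds 20 fixed genes and the 5 most abundant rows. Some genes that the rule takes are not reported here, though counts include them. The rule was applied again after median-ratio scaling. Other members of lists are named because they passed after that scaling, and were chosen after their values were seen.

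The procedure was tested on simulated libraries of 28403 tested rows with the real means, depths and scale factors and a dispersion of 0.1, for the comparison of HFD with control. With 200 rows changed, the deposited scale recovered 0% of the rows changed 2-fold and 0% of those changed 4-fold. Median-ratio scaling recovered 14% and 81%, with 2 false calls. The simulated libraries were distorted by the same factors that this scaling removes, so its advantage over the deposited scale was built in. The dispersion was set and not estimated from these libraries, so the rates do not give the power for the real data. Alternatives covered pseudocounts of 0.1 and 5, no filter, quantile normalization, summed rows, abundant RNAs left out, an adjusted p under 0.10, a fold of at least 2, other list tests and each library left out. Further ones, added after the data had been seen, covered median-ratio scaling, array weights, a stricter filter, rows with a symbol and totals without the 20 top rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.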

Results

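The series compares gene expression in gastric epithelial cells between mice fed a high fat diet and control mice. Total RNA from sorted cells was sequenced after removal of ribosomal RNA, with 4 HFD libraries (22, 23, 26 and 27) and 4 control libraries (15-17-18, 16, 19 and 20). Estimated depth ran from 31.4 to 46.0 M reads in HFD and from 16.4 to 63.2 M reads in control libraries (exact two-sided permutation p = 0.77).

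The libraries carried the RNA of acid-secreting and zymogenic gastric glands. Pgc, the gene of pepsinogen C (chromosome 17, 47726842 to 47734478, mm10), was among the 5 most abundant rows, with 21.21 ± 0.19 in HFD and 20.54 ± 0.46 in control (SD, n = 4 each). Atp4a and Atp4b, the subunits of the parietal cell proton pump, stood at 16.73 ± 0.32 and 15.49 ± 0.38 in HFD (SD, n = 4). The other 4 of the 5 most abundant rows were Esp38 (chromosome 17, 39950520 to 39955287), Lars2 (chromosome 9, 123366927 to 123462675), NEWGENE1689 and NEWGENE2102. Esp38, Lars2, NEWGENE1689 and NEWGENE2102 were highest in control 15-17-18, at 23.06, 21.59, 21.88 and 21.70 on the deposited log2 scale. Whether the reads of these 4 rows came from the genes they are named for was not tested. In that library the 20 most abundant rows took 83.4% of the total, against 58.5% in control 19, 26.1% and 40.6% in control 16 and 20, and 27.6% to 43.0% in HFD. Rows of 5S ribosomal RNA reached 182 ppm of the total in control 15-17-18 and 13.1 in control 19, against 2.44 to 6.41 in the other 6 libraries. Neither the share of the 20 rows (exact permutation p = 0.31) nor the 5S level (exact permutation p = 0.23) separated the groups beyond the spread between libraries.

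**Figure D1:**
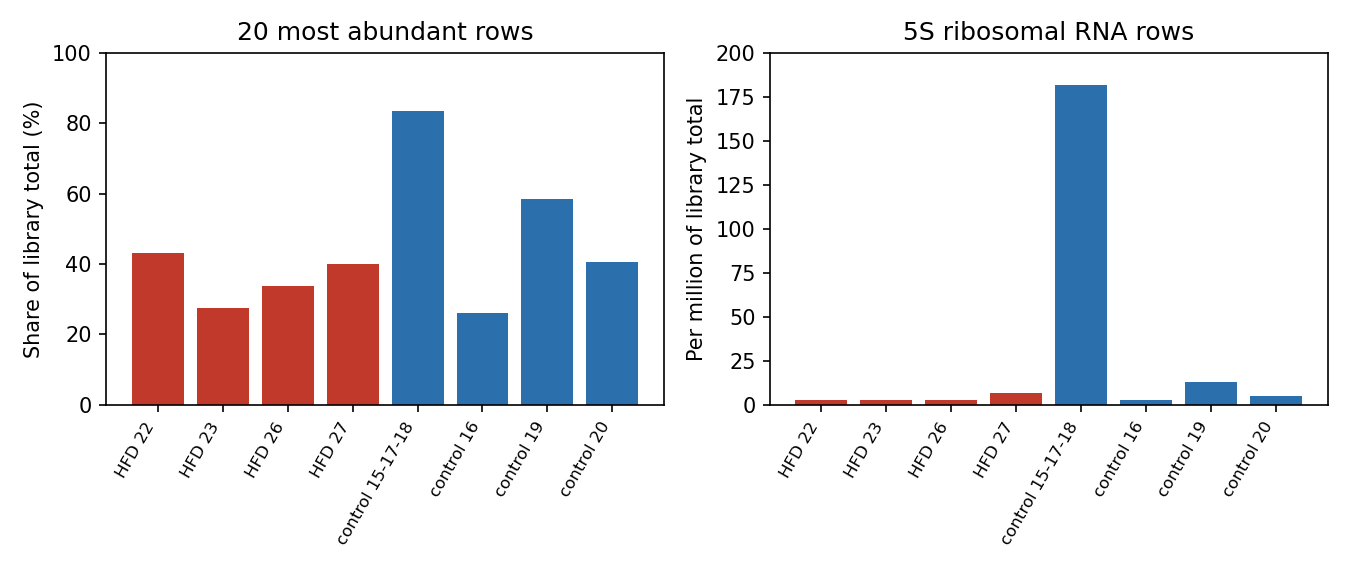
Share of each library's total taken by the 20 most abundant rows (left, percent) and level of the 5S ribosomal RNA rows (right, ppm of the library total), 1 bar per library, HFD in red and control in blue. Control 15-17-18 stands highest in both, at 83.4% and 182 ppm.

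Klf4, a zinc finger transcription factor of differentiating epithelia (chromosome 4, 55527137 to 55532475), fell in HFD by 1.42 ± 0.12 (SE, log2), from 13.24 ± 0.22 to 11.82 ± 0.07 (SD, n = 4 each; limma adjusted p = 0.0073), after median-ratio scaling. As deposited, Klf4 differed by -0.56 ± 0.75 (SE), with overlapping groups, and was not called (limma adjusted p = 0.61). Snora74a, a small nucleolar RNA within Snhg4 (chromosome 18, 35557030 to 35557227), was listed at 0 in all 4 HFD libraries and at 5.97, 10.33, 7.50 and 7.28 in control 15-17-18, 16, 19 and 20 on the deposited scale (limma adjusted p = 0.0058 after median-ratio scaling). After median-ratio scaling 3 rows were called among 27380 tested, with 2890 rows at an unadjusted p under 0.05. With 1 library left out, Klf4 and Snora74a passed in all 8 cases, and the count of 3 became 5 without control 16. Klf4 is in the list of immediate early and heat shock genes, which was not called (camera adjusted p = 0.15).

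On the deposited scale 16 rows were called, 13 higher and 3 lower in HFD, with 2630 at an unadjusted p under 0.05; after median-ratio scaling, and after quantile normalization, the split was 1 higher and 2 lower. On that scale the rule named, among the rows higher in HFD, Des, the intermediate filament of muscle, at 3.54 ± 0.77 (SE, log2), the predicted genes Gm7299 at 3.61 ± 0.83 and Gm2038 at 3.53 ± 0.79, and 4 rows without a gene name. The limma adjusted p was 0.019, 0.035 and 0.032 for Des, Gm7299 and Gm2038. After median-ratio scaling these became 2.71, 2.82 and 3.24, all with adjusted p above 0.05. The 3 lower rows were Snora74a and the microRNA precursors Mir218-1, within Slit2 (chromosome 5, 48223942 to 48224051), and Mir218-2, within Slit3 (chromosome 11, 35616816 to 35616925). Mir218-1 and Mir218-2 were called on the deposited scale (limma adjusted p = 0.019 and 0.0092) and not after median-ratio scaling, where they differed by -5.39 ± 0.71 and -5.79 ± 0.73 (SE; limma adjusted p = 0.079 and 0.071). Both precursors were listed at 0 in all HFD libraries. Mir218-1 stood at 4.42, 4.94, 4.76 and 5.53 and Mir218-2 at 5.05, 5.51, 4.87 and 5.87 in control 15-17-18, 16, 19 and 20. The precursors carry near-identical mature sequences, so their reads cannot be assigned with certainty. Vmn2r107, a vomeronasal receptor gene, 1 row without a symbol and 1 NEWGENE row filled the list of lower rows and missed the threshold, Vmn2r107 with a log2 difference of -3.16 ± 0.80 (SE; limma adjusted p = 0.060). Vmn2r107 was listed at 0 in HFD 23, and its difference was -1.62 without that library. The count of 16 became 1 without HFD 22, HFD 27 or control 15-17-18, 6 without HFD 23, 5 without control 19, 53 without HFD 26 and 104 without control 16.

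The rule applied after median-ratio scaling also named genes that missed the threshold. Acot1, an acyl-CoA thioesterase, was higher by 1.96 ± 0.23 (SE; limma adjusted p = 0.051). Spp1, which encodes osteopontin, differed by 1.93 ± 0.25 and Gper1, a membrane estrogen receptor, by 1.29 ± 0.17 (SE; limma adjusted p = 0.079 each). Prrc2a differed by -0.96 ± 0.11 (SE; limma adjusted p = 0.051), with a deposited difference of -0.10, and Klf3, a Kruppel-like factor, by -0.71 ± 0.10 (SE; limma adjusted p = 0.085). Klf3 had the opposite sign on the deposited scale, at 0.14.

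**Figure D2:**
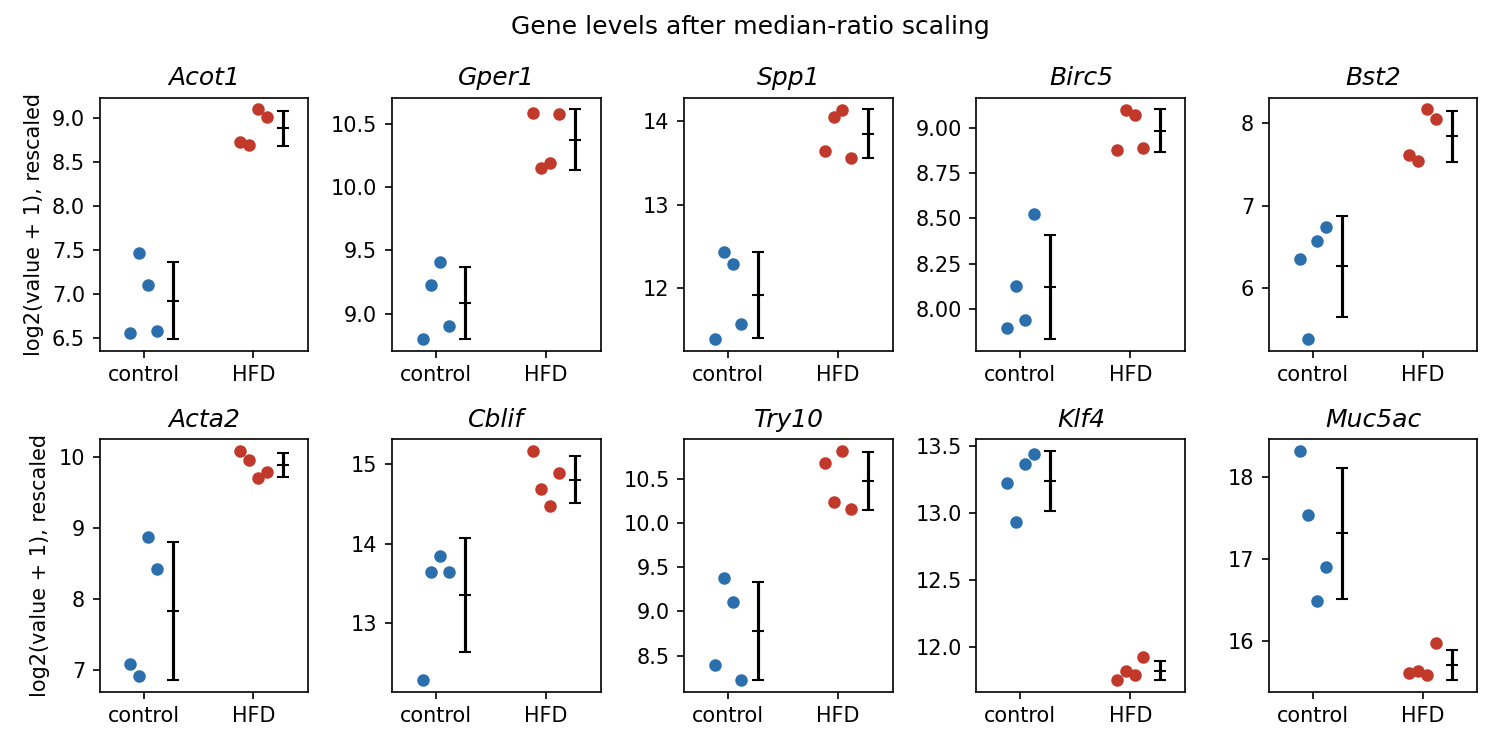
Levels of 10 genes as log2(value + 1) after median-ratio scaling, 1 point per library (4 control in blue, 4 HFD in red), with the mean and SD of each group in black; each panel has its own axis, which does not start at 0. The groups do not overlap for Acot1 and Klf4, whose means differ by 1.96 and -1.42.

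Of the 38 lists tested, 11 were called higher and 0 lower on the deposited scale, 11 and 4 after median-ratio scaling, and 13 and 1 after quantile normalization. With an estimated correlation 0 were called on either scale. Genes of the cell cycle were higher in HFD. Of 60 tested members of the list, 37 rose and 0 fell after median-ratio scaling, adjusted over the list alone, against 0 adjusted over all genes tested, and 58 of the 60 differences were positive. Cyclin A2 (Ccna2) rose by 0.78 ± 0.12, the mitotic kinesin Kif20a by 0.84 ± 0.15, survivin (Birc5) by 0.86 ± 0.17, the replication licensing factor Mcm7 by 0.71 ± 0.14 and the checkpoint kinase Chek1 by 1.14 ± 0.41 (SE, log2, n = 4 each). Mki67, the proliferation marker fixed beforehand, was not among them, at -0.05 ± 0.32 (SE). Camera called the list higher on both scales (adjusted p = 5.1e-21 after median-ratio scaling and 5.3e-08 as deposited), and with an estimated correlation the adjusted p was 0.38 and 0.999. Fry gave an adjusted p of 0.023 after median-ratio scaling and 0.30 as deposited. After that scaling fry called this list alone among the 38. The count of 37 became 17, 14 and 24 without HFD 23, HFD 26 and HFD 27, and 0 on the deposited scale. Over the 35 divisions of the libraries into groups of 4, 2, the real one included, had a list with at least 37 members called.

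Within the list of fatty acid uptake, oxidation and PPAR targets, 4 of 57 tested members rose and 1 fell, adjusted over the list alone, against 1 and 0 over all genes tested. Among those that rose were Acot1, its neighbour Acot2, at 1.21 ± 0.22, and the fatty acid binding protein gene Fabp1, at 1.76 ± 0.47 (SE). Acot1 and Acot2 are close paralogs, and reads could be split between them. Ppard, a lipid-sensing nuclear receptor, was the member that fell, by 0.52 ± 0.12 (SE), while its deposited difference was 0.33. The list was called higher as a whole (camera adjusted p = 0.012, and adjusted p = 0.54 with an estimated correlation), but not without control 15-17-18 (adjusted p = 0.18), HFD 26 (adjusted p = 0.094) or control 19 (adjusted p = 0.12). The count of 5 members became 3 without any 1 of the HFD libraries or without control 20, and 8 without control 19.

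In the list of fibroblast and smooth muscle markers, 8 of 20 tested members rose and 0 fell, adjusted over the list alone, with 0 over all genes tested; on the deposited scale the counts were 10 and 1, the latter being Des. All 8 were among the 9 muscle genes of the list, and 0 of the other 11 members passed, a division of the list made after its calls had been seen. Of those 11 members 10 had a positive difference, with a median of 0.41, against a median of 1.85 for the muscle genes. Smooth muscle actin (Acta2) rose by 2.05 ± 0.42, Actg2 by 1.81 ± 0.40 and calponin (Cnn1) by 2.19 ± 0.52 (SE, n = 4 each), while the collagens Col1a1, Col1a2 and Col3a1 were at -0.14 ± 0.55, 0.28 ± 0.54 and 0.11 ± 0.52 (SE), Col1a1 with 0.72 as deposited. These collagens all lay below the median of 0.41 of the 11 members outside muscle. The list was called higher (camera adjusted p = 7.2e-07, and adjusted p = 0.45 with an estimated correlation). Without control 19, whose score of 8.34 lay among the HFD libraries (8.03 to 8.72), 13 members passed, 4 of them outside muscle (Lum, Sparc, Dcn and Pdgfrb). In the list of forestomach squamous markers, 23 of 25 differences were positive, 0 members passed after median-ratio scaling and 12 on the deposited scale, adjusted over the list alone. The keratins Krt4 and Krt13 were called on the deposited scale over all genes, at 3.43 ± 0.78 and 3.24 ± 0.75 (SE; limma adjusted p = 0.034 and 0.039), and stood at 2.68 ± 0.95 and 2.46 ± 1.01 after median-ratio scaling, where neither was called. The basal keratin Krt5 was at 2.13 ± 1.12 (SE). Camera called this list higher (adjusted p = 3.0e-04, and adjusted p = 0.45 with an estimated correlation).

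Interferon-induced genes were higher as a list (camera adjusted p = 3.4e-09, and adjusted p = 0.45 with an estimated correlation), with 48 of 53 differences positive and 5 members higher, adjusted over the list alone, against 0 over all genes tested. Those 5 were Bst2 (tetherin), at 1.58 ± 0.32, Oas2 at 1.93 ± 0.52, Oasl2 at 1.15 ± 0.27, Rtp4 at 1.25 ± 0.29 and Ifitm3 at 1.86 ± 0.47 (SE, n = 4 each). The count of 5 became 0 without HFD 22, HFD 26, HFD 27 or control 15-17-18, 1 without control 16 and 12 without control 20, and it was 10 on the deposited scale.

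Of 13 tested chief cell markers, 4 rose and 0 fell, adjusted over the list alone, with 0 over all genes tested. They were Cblif, the gene of gastric intrinsic factor, at 1.46 ± 0.33, the cholecystokinin receptor gene Cckar at 0.98 ± 0.22, the secretory transcription factor Bhlha15 at 0.87 ± 0.19 and Pgc at 0.67 ± 0.22 (SE, n = 4 each). Cym, the gene of chymosin, was at 1.51 ± 0.91 (SE) and did not pass. The list was called higher (camera adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation), and 7 members passed without control 19 and 2 on the deposited scale. Of 22 tested pancreatic acinar markers, 4 rose and 0 fell, adjusted over the list alone, with 0 over all genes tested. These were the trypsins Try10, at 1.70 ± 0.27, Try5, at 1.38 ± 0.35, and Try4, at 1.11 ± 0.32, and colipase (Clps), at 1.31 ± 0.25 (SE); trypsin genes are similar enough to share reads. Zg16 was at 3.25 ± 1.13 (SE) and did not pass. Of the 22 differences 15 were positive and 7 were not. Cpa1, near the floor, Cela2a and Cel were at -0.24 ± 0.79, -0.20 ± 0.46 and -0.42 ± 0.32 (SE). Camera called the list higher (adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation), but not without control 20 (adjusted p = 0.068). On the deposited scale 7 members passed, and 2 passed without HFD 22, HFD 26, control 15-17-18 or control 20. Among 28 intestinal markers, Spink4 at 1.38 ± 0.26, Fabp1, and the antimicrobial lectin Reg3g at 3.18 ± 0.87 (SE) rose and 0 fell, adjusted over the list alone, with 0 over all genes tested and 7 over the list on the deposited scale. The count of 3 became 1 without any 1 of the HFD libraries or without control 20. Fcgbp, a mucus protein gene, was called on the deposited scale at 3.58 ± 0.74 (SE; limma adjusted p = 0.010) and stood at 2.73 ± 1.14 after median-ratio scaling (adjusted p = 0.47). The list was called higher (camera adjusted p = 0.0066, and adjusted p = 0.45 with an estimated correlation), but not without HFD 23 (adjusted p = 0.069).

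**Figure D3:**
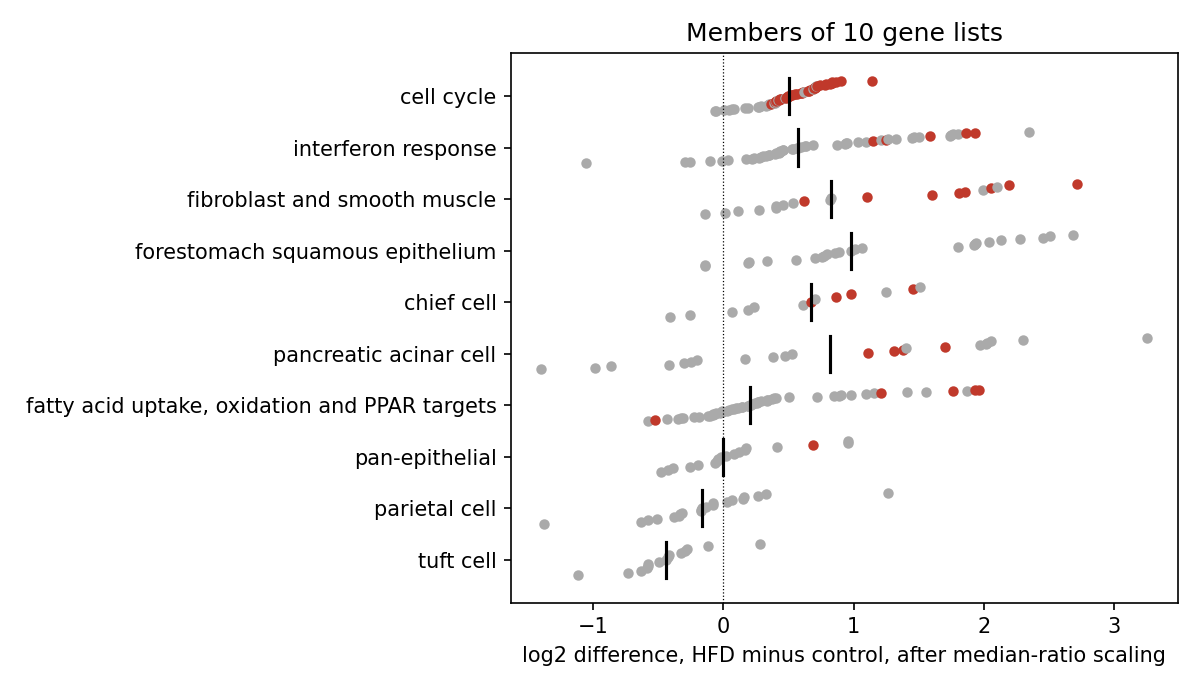
Difference between HFD and control (log2, after median-ratio scaling) of each tested member of 10 lists, 1 point per gene, red where it passed an adjusted p of 0.05 over the list alone and grey otherwise; black bars mark list medians, and the dotted line marks 0. In the cell cycle list 37 of 60 points are red, and in the tuft cell list 0 are.

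In the list of structured and non-polyadenylated RNAs, 7 of 27 tested members rose and 0 fell, adjusted over the list alone, with 0 over all genes tested. All 7 were among the 11 histone genes tested in the list, a count taken after its calls had been seen, and only H1f3 and H1f4 passed without control 15-17-18. The linker histones H1f3 and H1f5 were at 1.06 ± 0.17 and 1.37 ± 0.42 (SE). The list was called higher (camera adjusted p = 0.0010, and adjusted p = 0.45 with an estimated correlation), but not with control 15-17-18 left out (adjusted p = 0.059). The count of 7 became 2 without control 15-17-18, 3 without HFD 26 or control 20, 4 without HFD 27 and 0 on the deposited scale. The lists of cytosolic ribosomal proteins and of nuclear oxidative phosphorylation genes were called higher (camera adjusted p = 1.4e-06 and 1.9e-05, and adjusted p = 0.54 with an estimated correlation for each), with medians of 0.42 and 0.32, or 0.25 and 0.12 without control 15-17-18, and with 0 members called in either, over all genes or adjusted over the list alone. The members with the smallest p on the deposited scale were Rps21 at 1.41 ± 0.44, Rps16 at 0.99 ± 0.30, Uqcrq at 0.86 ± 0.25 and Ndufa3 at 0.91 ± 0.36 (SE). All of them lie above the medians of their lists. The oxidative phosphorylation call was lost with control 15-17-18 left out (adjusted p = 0.068).

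Lists called lower after median-ratio scaling, and not on the deposited scale, were those of tuft cells, parietal cells, leptin and JAK-STAT3 signalling, and insulin, PI3K and mTOR signalling (camera adjusted p = 8.2e-05, 0.012, 0.0088 and 0.026, and adjusted p = 0.45, 0.46, 0.38 and 0.38 with an estimated correlation). After quantile normalization only the tuft cell list was still called lower (camera adjusted p = 4.6e-05). The parietal, leptin and insulin lists were not (camera adjusted p = 0.31, 0.075 and 0.31). Of 15 tuft cell markers 1 had a positive difference after median-ratio scaling, and the median was -0.44, or -0.28 without control 15-17-18. The tuft cell score was 9.06 in that library, 7.72 to 8.26 in the other controls and 7.69 to 7.90 in HFD, and its difference of -0.45 became -0.20 without it. Ltc4s and Gng13, at 0.28 ± 0.36 and -0.11 ± 0.38 (SE), had the smallest p on the deposited scale. The parietal cell median was -0.16, or -0.27 without control 15-17-18, with Car2 at 0.33 ± 0.16 and Aqp4 at 0.27 ± 0.22 (SE). The leptin list had a median of -0.07, and the insulin list one of -0.11; both lists pointed up on the deposited scale without being called. Deposited medians of the tuft, parietal, leptin and insulin lists were 0.42, 0.69, 0.78 and 0.75, all positive and below the median tested row. The parietal call was lost without HFD 22, control 16 or control 20 (adjusted p = 0.11, 0.065 and 0.084), the insulin call without HFD 27, control 16 or control 20 (adjusted p = 0.055, 0.065 and 0.085), and the leptin call without control 20 (adjusted p = 0.084). In the leptin list Cish, an inhibitor of cytokine signalling, fell by 0.62 ± 0.12 (SE), adjusted over the list alone, with a deposited difference of 0.24, while Mcl1 was at 0.29 ± 0.51 (SE). Grb10 and Ddit4 of the insulin list were at 1.32 ± 0.46 and 0.64 ± 0.16 (SE). Cish was the only member of these 4 lists that passed over its list, and no member passed over all genes tested.

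Of the genes fixed beforehand, Muc5ac, the secreted mucin of surface cells, fell by 1.61 ± 0.35 (SE), from 17.31 ± 0.80 to 15.70 ± 0.18 (SD, n = 4 each), adjusted over the list of surface mucous cell markers alone and after median-ratio scaling. Over all genes it did not pass (limma adjusted p = 0.20). On the deposited scale it differed by -0.75 ± 0.77 (SE; limma adjusted p = 0.54), with overlapping groups and 0 members of the list called, and that list was not called (camera adjusted p = 0.066). Epcam, the epithelial adhesion molecule, rose by 0.69 ± 0.14 (SE), adjusted over the pan-epithelial list alone, with adjusted p = 0.20 over all genes. The pan-epithelial list was not called (camera adjusted p = 0.54), and 9 of its 18 differences were positive. Its member Cdh1 was lower, at -0.42 ± 0.12 (SE), and did not pass. Lep was listed at 0 in control 15-17-18, 19 and 20 and stood at 2.56 in control 16 and at 0.88, 2.11, 0.97 and 1.67 in HFD 22, 23, 26 and 27. All of these Lep values are near the floor, and the difference was -0.12 after quantile normalization. Lepr differed by 0.60 ± 0.60 (SE). Socs3 and Stat3 differed by 0.04 ± 0.24 and -0.14 ± 0.11 (SE). Atp4a and Atp4b differed by -0.17 ± 0.22 and -0.17 ± 0.26, Gkn1 by -0.12 ± 0.29, Muc6 by -0.27 ± 0.60, Tff2 by 0.12 ± 0.33 and Ghrl by 0.13 ± 0.28 (SE). The intestinal genes Cdx2, Muc2 and Tff3 differed by -0.74 ± 1.12, -1.62 ± 1.01 and 1.33 ± 1.05, and the leukocyte gene Ptprc by 0.31 ± 0.48 (SE). After median-ratio scaling, none of the genes fixed beforehand other than Muc5ac, Epcam, Cblif and Pgc passed, over all genes or over their list; Krt5 passed over its list on the deposited scale. Stat3, Atp4a, Atp4b, Gkn1, Muc6, Cdx2 and Mki67, and Gng13 of the tuft cell list, had the opposite sign on the deposited scale.

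Scores of the 17 marker lists were compared to see whether the makeup of the sorted cells differed. The forestomach score was higher in all 4 HFD libraries than in all 4 controls, at 6.38 ± 0.42 against 5.16 ± 0.92 (SD, n = 4 each; exact two-sided permutation p = 0.029, the smallest possible), and its adjusted p was 0.24. The fibroblast and smooth muscle score was 8.36 ± 0.35 against 7.28 ± 0.80 (SD, n = 4 each; exact permutation p = 0.086), the chief cell score 11.14 ± 0.24 against 10.54 ± 0.34 (SD, n = 4 each; exact permutation p = 0.057) and the pan-epithelial score 10.84 ± 0.12 against 10.75 ± 0.07 (SD, n = 4 each; exact permutation p = 0.26). On the deposited scale the chief, mucous neck, forestomach, fibroblast and smooth muscle, and pancreatic scores separated the groups completely (exact permutation p = 0.029 each), with an adjusted p of 0.097. No score passed the adjusted threshold on either scale, but with 17 lists and 4 libraries per group at least 10 would have to reach the smallest possible p together, so this says little about the makeup of the cells.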

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

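The tests of the deposited scale as a source of the smooth muscle difference, of control 15-17-18, of library totals and of the host genes were chosen after the results they bear on had been seen. The division test over all lists was added after that of the cell cycle list had been seen. The test of smooth muscle cells was chosen after the pattern, and after a first version, which could not have failed, and a second, on the 8 genes that passed alone, had been run and seen. In 226 groups of 4 libraries, 13 held a library whose gap to its nearest neighbour exceeded Dixon's 95% limit, where chance gives about 1 in 20 groups, or 11.3.

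The level of 5S ribosomal RNA in control 15-17-18 stood apart from the other controls (gap 0.942 of the range), at 182 ppm of the total against 2.69 to 13.1, and that of HFD 27 from the other HFD libraries (gap 0.866), at 6.41 against 2.44 to 2.97. Control 15-17-18 was also apart for Atp4a (gap 0.928) and Cblif (gap 0.869), being lower than the other controls in both. HFD 23 was apart, and higher, for Mcl1 (gap 0.882), Socs3 (gap 0.859) and the pan-epithelial score (gap 0.911). HFD 27 was apart for Muc5ac (gap 0.869), HFD 22 for Actg2 (gap 0.893) and HFD 26 for H1f4 (gap 0.852), all higher. Control 20 was apart for H1f3 (gap 0.8294), where it was lower, and for Mcm7 (gap 0.830), where it was higher. Control 16 was the only control with Lep above 0 (gap 1 of the range).

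The median tested row was 0.90 higher in HFD on the deposited scale. With totals taken without the 20 most abundant rows the median was 0.35, and without control 15-17-18 it was 0.32, each less than the deposited shift but above 0.30, the level set for calling either the whole cause. Both may contribute, and neither was excluded. More RNA per cell in HFD-fed mice stays open, because the library totals differ by 0.0039% and so hold no information on it.

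Of the fibroblast and smooth muscle markers, 8 were higher in HFD, all of them muscle genes. The deposited scale as the whole source is argued against by the 8 members that passed after median-ratio scaling. A lower share of epithelial cells, which would raise the markers of other cell types alike, was not settled: the score of the list exceeded the leukocyte score by 0.76 more in HFD (exact permutation p = 0.26). The pan-epithelial score, which such a share would lower, was 0.093 higher in HFD (exact permutation p = 0.26). The leukocyte score was 0.33 higher (exact permutation p = 0.34). More smooth muscle cells among the sorted cells cannot be told apart from other sources: over all 9 muscle genes, Lmod1 included, the mean Pearson r within groups was 0.698, just short of the 0.7 set for it, with 0.80 for the 8 that passed and 0.64 for the other 11 members, where 1000 random lists had a 95th percentile of 0.17. A sort for epithelial cells should remove such cells, whose abundant gene Acta2 stood at 9.88 ± 0.17 in HFD (SD, n = 4) against 12.39 ± 0.12 for Epcam, Myl9 and Mylk are also expressed by epithelia, and a change of expression by diet in these cells stays open.

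Snora74a, Mir218-1 and Mir218-2 were listed at 0 in all 4 HFD libraries and at 16 or more, on the linear scale, in all controls. Loss of rows from single tables regardless of the group is argued against, since the highest number of such rows in the other 69 divisions of the libraries was 0, against 3. Lower transcription of Snhg4, which holds Snora74a, is argued against by its difference of 0.28, with a lower 95% limit of -0.68 on the log2 scale. A lower level of the host RNA as the whole cause is argued against for Mir218-1, which needs a fall of at least 4.58 to be listed at 0 (a level of at most 1) where the lower limit of Slit2 was -3.25 (difference -1.05 ± 0.90, SE), and for Mir218-2, which needs 4.99 where that of Slit3 was -1.67 (0.18 ± 0.76, SE), all log2 after median-ratio scaling; a part from a lower Slit2 is not excluded. Slit2 stood at 10.54 in control 15-17-18, against 6.81 to 7.69 in the other controls and 5.88 to 7.91 in HFD. The difference of Slit2 thus rests largely on that library, and it was -0.19 as deposited. A difference between the groups in how the 3 rows were counted, and an effect of diet on these small RNAs, stay open and were not tested.

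Other divisions of the 8 libraries, 35 in all with the real one, bear on each count. On the deposited scale 5 of 35 called at least the real 16 rows, with 50 in the highest other, so chance cannot be excluded; the division of 50 called 0 after median-ratio scaling, so it may reflect a structure of the libraries or the deposited scale, and which was not tested. After median-ratio scaling the real division called 3 rows and the highest other 0, which is 1 of 35. That is the smallest share possible, for a scaling chosen after the data had been seen. Snora74a, 1 of the 3, was listed at 0 in the HFD libraries alone, so it could separate fully in the real division only. As 1 of several such counts, this does not exclude chance. For gene lists chance cannot be excluded: 12 of 35 divisions called at least the real 11 lists, with 18 in the highest other, and after median-ratio scaling 4 of 35 called at least 15, with 19 in the highest other. For cell cycle members after median-ratio scaling the real count was 37 and the highest other 1, which is 1 of 35, but this list was singled out as the strongest of 38. Taking the highest count over all lists in each division, 2 of 35 reached 37, with 40 in the highest other, so chance cannot be excluded.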

How the results depend on the processing

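Alternatives with median-ratio scaling, array weights, the stricter filter, symbols only or other totals, and quantile normalization for lists, were chosen after the data had been seen; the rest were planned. The 16 rows called became 25 with a pseudocount of 5, 9 with no filter, 3 with quantile normalization, 88 at an adjusted p under 0.10, 3 with median-ratio scaling (also 3 with it and either control 15-17-18 or HFD 23 left out), 7678 with array weights, 10 with at least 1 ppm of the total in 4 libraries and 1 with totals without the 20 top rows, and ran from 1 to 104 with 1 library left out. They stayed within 1.5 times with a pseudocount of 0.1, summed rows, abundant RNAs left out, a fold of at least 2, symbols only and median-ratio scaling with array weights, although the last gave 9 higher and 12 lower against 13 and 3. The 11 lists called became 0 with an estimated correlation, 0 with fry, and 0 with median-ratio scaling and an estimated correlation, and ran from 8 to 13 with 1 library left out. No cell type score was called under any alternative run, which the design nearly fixes, since at least 10 of 17 would have to reach the smallest p together, so this does not speak for stability. The 37 cell cycle members called after median-ratio scaling became 0 on the deposited scale and ran from 14 to 36 with 1 library left out; after that scaling the rows called ran from 2 to 5 and the lists from 12 to 19. The count models, their scalings and filters, voom weights and the surrogate variable were not run, since the tables hold no counts. No paired analysis was possible because the groups share no replicate number. Of the other values of named genes, 1695 kept direction and side of the threshold, 75 passed it only under the alternative, 77 lost it and 90 changed sign, none of them called on the deposited scale; of these, Klf3 was called lower with array weights on both scales and Ppard with them on the deposited scale. Those that changed sign follow as log2 differences. After median-ratio scaling they were Klf3 -0.71, Gng13 -0.11, Stat3 -0.14, Atp4a -0.17, Atp4b -0.17, Gkn1 -0.12, Muc6 -0.27, Cdx2 -0.74, Mki67 -0.052, Col1a1 -0.14, Ppard -0.52 and Cish -0.62. After that scaling with control 15-17-18 left out they were Klf3 -0.78, Gng13 -0.024, Stat3 -0.17, Atp4a -0.40, Atp4b -0.42, Gkn1 -0.22, Tff2 -0.17, Ppard -0.51 and Cish -0.61. After it with HFD 23 left out they were Klf3 -0.73, Mcl1 -0.28, Gng13 -0.29, Socs3 -0.22, Stat3 -0.21, Atp4a -0.036, Atp4b -0.036, Muc6 -0.62, Cdx2 -1.08, Mki67 -0.10, Col1a1 -0.33, Col3a1 -0.084, Ppard -0.53 and Cish -0.60. After it with array weights they were Klf3 -0.72, Mcl1 -0.19, Gng13 -0.25, Socs3 -0.10, Stat3 -0.21, Atp4a -0.18, Atp4b -0.24, Gkn1 -0.23, Muc6 -0.12, Tff2 -0.063, Ppard -0.50 and Cish -0.65. With array weights on the deposited scale they were Klf3 -0.67, Cym -0.66, Mcl1 -0.076, Stat3 -0.10, Atp4a -0.013, Muc6 -0.090, Tff2 -0.53, Muc2 0.43, Esp38 0.16, NEWGENE1689 0.83, Ppard -0.51 and Cish -0.34. After quantile normalization they were Klf3 -0.64, Gng13 -0.24, Lep -0.12, Socs3 -0.035, Stat3 -0.083, Muc6 -0.0041, Cdx2 -1.05, Col1a1 -0.21, Ppard -0.49 and Cish -0.65. With totals without the 20 top rows they were Klf3 -0.47, Muc6 -0.018, Cdx2 -0.52, Ppard -0.27 and Cish -0.37. With 1 library left out, Prrc2a -0.65 to 0.22, Klf3 -0.51 to 0.50, Atp4a -0.14 to 1.13, Atp4b -0.15 to 1.19, Cdx2 -0.36 to 0.84, Muc2 -1.45 to 0.049, Ppard -0.24 to 0.67, Cish -0.35 to 0.64 and Slc7a11 -0.69 to 0.44 was the range. Scaling to another reference shifts all genes of a library together, and the cause was otherwise not tested. Control 19 had the lowest estimated depth and control 15-17-18 the most rows at 0, and which of them limits the low genes most was not tested.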

Other observations

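The test of ribosomal RNA was chosen after the levels it uses had been seen. Genes of the unfolded protein and integrated stress response moved in both directions after median-ratio scaling, a scaling chosen after the data had been seen. The list was not called (camera adjusted p = 0.056), and 2 of 33 tested members rose and 1 fell, adjusted over the list alone. Pdia6, a protein disulfide isomerase of the endoplasmic reticulum, rose by 0.51 ± 0.09 and Psat1, an enzyme of serine synthesis, by 0.85 ± 0.20 (SE, log2). Slc7a11, the cystine transporter gene, was lower by this scaling, at -0.89 ± 0.24 (SE), while its deposited difference was -0.04 ± 0.76 (SE) and turned to 0.44 without control 16. As deposited, 0 members of the list passed. Dnajb9 was at 0.91 ± 0.80 (SE). Among 35 gut hormone and receptor genes, Nucb2, the precursor of nesfatin, rose by 1.01 ± 0.19 and Cckar by 0.98 ± 0.22 (SE), adjusted over the list alone. The list itself was not called (camera adjusted p = 0.34), and the low hormone genes Pyy and Calca were at 2.89 ± 1.08 and 2.55 ± 0.77 (SE).

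Ribosomal RNA left in the library may go with a low level of the typical gene, as a hypothesis found in these libraries. Over the 8 libraries, the log2 level of 5S ribosomal RNA and the median-ratio factor had a Pearson r of -0.98 (exact permutation p = 0.0021) and a Spearman rho of -0.90 (exact permutation p = 0.0046), the only relation between library measures that was computed. Without control 15-17-18 and control 19, the 2 libraries farthest from the median, r was -0.54 over 6 libraries (exact permutation p = 0.27), so the relation rests largely on those libraries. The 5S rows hold a small part of the total, and the identity of the most abundant rows, Esp38, Lars2 and the NEWGENE rows among them, was not tested.

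Several rows were listed at 0 in 1 library only while all others stood above 30 on the linear scale. There were 24 such rows in HFD 23, 18 in control 15-17-18 and 0 in each of the other libraries.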
